A study of Mus musculus with 12 samples.

How the data were processed

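The RNA of 12 libraries was compared, 3 from each of 4 cell populations sorted from CD-1 mouse pups at postnatal day 3. Per the labels, perivascular fat of the thoracic aorta and inguinal white fat were digested with collagenase D and dispase II, cells were sorted, and libraries were made with an ultra-low-input SMART-Seq kit that selects poly(A) RNA. Inguinal cells were sorted as DPP4+ progenitors and ICAM1+ preadipocytes. The surface markers that defined the perivascular populations are not given in the sources used here. Per the labels, replicates with the same number came from the same pools of mice, so a replicate is a pool and not an animal.

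The submitters' processing notes name STAR 2.5.2a for alignment to mm10 and DESeq2 1.26.0 for normalisation. The counting tool, its annotation and whether strand was used are not given in the sources used here. The deposited table of raw values holds one count per gene and library. The table the authors normalised holds a signal for each gene, the raw count divided by 1 size factor per library. The third deposited table holds regularised log2 values. The raw counts were used for all comparisons, and the regularised log2 values only for a check of how libraries group. The columns of all 3 tables were assigned to the samples by name, and 0 columns were left over. The counts cover 31099 genes, of which 31074 have an identifier in GENCODE release 21 for mouse, and the table gives a symbol for 20387 and none for 10712. Coordinates and exon overlaps come from that release. Genes whose exons overlap those of another gene are uncertain where strand was not used, as for Tagln (67.9% of its exon length).

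Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 under R 4.3.3. Genes were kept by edgeR's filterByExpr with the groups and a minimum count of 10, which left 18855. Libraries were scaled by TMM factors, and the 12 libraries were fitted in 1 quasi-likelihood model with a mean per group (glmQLFit, glmQLFTest). The tests are two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, with a call at an adjusted p under 0.05. The 5 comparisons were perivascular against DPP4+ inguinal progenitors, perivascular against ICAM1+ inguinal preadipocytes, preadipocytes against progenitors in each depot, and the interaction of depot and stage. Genes called in both depot or both stage comparisons were counted beside the number expected for independent lists. Log2 CPM for principal components and plots used a prior count of 2. The samples, groups, comparisons, tests, gene lists, the rule for naming genes and the alternative settings other than those named last were set before the data were examined.

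The named genes follow 5 parts. The first takes the 6 highest and 6 lowest log2 fold changes of each comparison (4 and 4 for the interaction) among called genes with a mean of at least 10 CPM in the higher group and all libraries of one group above those of the other, a separation that chance gives 10% of genes in 3 against 3. Predicted and unnamed genes were passed over. The second takes Dpp4, Icam1 and Pdgfra, and the third Ucp1, Prdm16, Ebf2, Pparg, Cebpa, Adipoq, Fabp4, Pi16, Cd55, Myh11, Acta2 and Tagln, whatever their values. The fourth takes up to 4 called genes with the largest changes from each list described, and the fifth the 2 most abundant genes of lists without a call. From the candidates of the fourth part, the text prefers genes whose call held when any 1 library was left out. A fold against a group without a count is a bound set by a floor of 3 counts over the group, and with 1 to 3 counts a ratio with its 95% counting interval. Such intervals and floors cover counting error only, because the reads carry no molecular identifiers.

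The 33 gene lists, written from textbook knowledge, were: progenitor, preadipocyte, adipocyte and lipid, thermogenic, nuclear oxidative phosphorylation, mitochondrially encoded, Hox paralogue groups 1 to 5, 6 to 8 and 9 to 13, limb and body wall transcription factors, cardiac outflow tract and neural crest transcription factors, fibrillar and elastic matrix, basement membrane, TGF-beta, BMP and Wnt signalling, retinoid, IGF and growth, chemokine and complement, interferon response, cell cycle, dissociation and early response, smooth muscle, pericyte, endothelial, haematopoietic, erythroid, Schwann and neural, mesothelial, epithelial, skeletal myogenic, cartilage and tendon, and thymus. The progenitor list holds Dpp4 and the preadipocyte list Icam1, which the inguinal sorts used. Each list was tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and the called members were counted with adjustment over all genes and adjusted over the list alone. Of 165 list tests 83 were called, and 25 of these were also called with an estimated correlation. The estimate was 0.313 for cell cycle genes between the progenitors, whose adjusted p was 0.00753 with it instead of 1.94e-42. Adjusted p of lists below are at the preset correlation unless said otherwise, and very small ones rest on that setting. In the interaction, list medians are also given without genes at the count floor (3 or fewer counts in any group).

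Total counts per library ran from 15614628 to 25674461, with 23622 to 28930 genes detected. The mean TMM factors were 0.784 in DPP4+ progenitors, 1.02 in ICAM1+ preadipocytes, 1.06 and 1.19 in the perivascular groups. The method was tested on simulated data with the means, spread and depth of these libraries, in which 200 of 18855 genes were changed. At a 4-fold change it recovered 72.7% in the comparison of progenitors, 95.5% in that of preadipocytes, 90.9% for the perivascular stages, 83.3% for the inguinal stages and 57.6% for the interaction. At 2-fold it recovered 25.4%, 20.9%, 32.8%, 26.9% and 1.49%, and at 1.5-fold 1.49%, 5.97%, 4.48%, 1.49% and 0%. False calls numbered 4, 2, 1, 2 and 4, and 0 calls had the wrong direction.

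The pairing by pool was checked on the deviations of each library from its group mean. Libraries of the same pool had a median correlation across genes of 0.00931 (18 pairs) and libraries of other pools 0.00872 (36 pairs). As planned, the replicate number was left out of the fit and added as a block in an alternative. The block lost 464 to 811 calls per comparison and gained 44 to 110, so pool effects are not excluded. The other alternatives were median-of-ratios size factors, library totals as the scale, no filter on low counts, a stricter filter (at least 5 CPM in 3 libraries), each library left out in turn, DESeq2, limma-voom with quality weights, a fit of the 2 groups compared alone, an adjusted p under 0.01, a change of at least 2-fold, limma's fry, and camera with an estimated correlation. Chosen after seeing the data were a fit without 3 libraries that stood apart (both perivascular libraries of pool 1 and inguinal progenitor library 2) and the replicate block joined with an estimated correlation.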

Results

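The series measured RNA in cells sorted from the fat around the thoracic aorta (perivascular fat) and from inguinal white fat of CD-1 mouse pups at postnatal day 3, with the sexes mixed. The libraries fell into 4 groups of 3: perivascular progenitors, perivascular preadipocytes, inguinal DPP4+ progenitors and inguinal ICAM1+ preadipocytes. Each library came from a pool of mice. Total counts were 17454519 ± 1082912 (SD, n = 3) in perivascular progenitors, 16719313 ± 1083571 in perivascular preadipocytes, 16764986 ± 796502 in DPP4+ progenitors and 20277155 ± 5040229 in ICAM1+ preadipocytes. Library totals ran from 15614628 to 25674461. Levels below are TMM-scaled CPM (counts scaled to a common library size), as mean ± SD of 3 libraries, and changes are log2 fold changes with the adjusted p of the edgeR test over 18855 genes. Coordinates are those of mouse build mm10.

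The first principal component held 68.5% of the variance of the 500 most variable genes and the second 14.9%. With these genes, all 12 libraries had their nearest library in their own group, by correlation across genes. With all tested genes or the 2000 most variable, this held for 11, since perivascular progenitor library 1 was nearest to perivascular preadipocyte library 1. Fibrillar and elastic matrix genes took 33.3 ± 0.80% of the counts in DPP4+ progenitors, 23.7 ± 1.60% in ICAM1+ preadipocytes, 24.6 ± 4.92% in perivascular progenitors and 10.04 ± 5.65% in perivascular preadipocytes. Col3a1 alone took 16.1% of the counts in DPP4+ progenitors and 3.35% in perivascular preadipocytes.

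**Figure D1:**
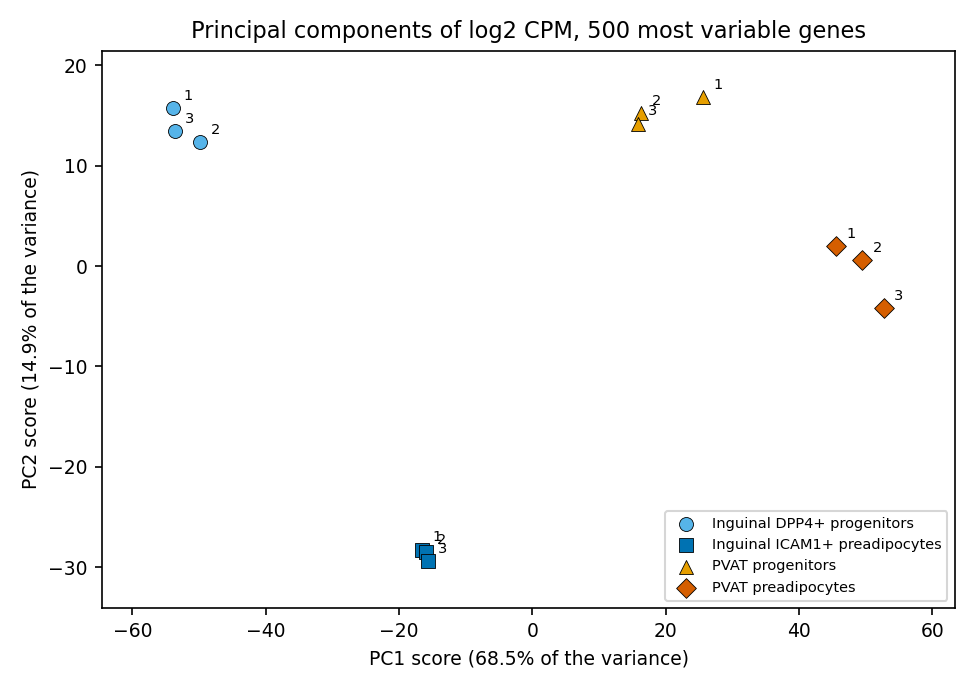
First principal component (horizontal, 68.5% of the variance) against the second (vertical, 14.9%) of log2 CPM of the 500 most variable genes. Each point is 1 of the 12 libraries, coloured by group and numbered by replicate, and perivascular progenitor library 1 lies at 25.6 on the first component against 16.4 and 15.8 for the other libraries of its group.

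Perivascular progenitors were set against DPP4+ inguinal progenitors of the same age. The perivascular sort markers are not given, so in both depot comparisons a difference between depots may also be one between sort gates. The design cannot tell these apart. Perivascular progenitors held more Cxcl13, a B cell chemokine (chromosome 5, 95956951 to 95961068), at 50.4 ± 14.9 CPM against 0.130 ± 0.117 (log2 8.56, adjusted p = 1.41e-07). The inguinal progenitors held more Hoxc10, a posterior Hox gene (chromosome 15, 102966796 to 102971893), at 14.2 ± 0.990 CPM against 0.0715 (log2 -7.49, adjusted p = 5.51e-08). Ucp1, the uncoupling protein of thermogenic fat (chromosome 8, 83290352 to 83298452), was at 5.80 ± 2.71 CPM in perivascular and 0.508 ± 0.243 in inguinal progenitors (log2 3.50, adjusted p = 0.000809). Pparg, the nuclear receptor that drives adipogenesis (chromosome 6, 115360951 to 115490399), was higher in perivascular progenitors at 44.7 ± 6.51 against 14.4 ± 3.64 CPM (adjusted p = 0.000546). Cd55 and Pi16, surface markers of interstitial progenitors, were lower there, Cd55 (chromosome 1, 130439027 to 130462744) at 90.5 ± 4.34 against 992 ± 51.0 CPM and Pi16 (chromosome 17, 29317680 to 29330593) at 773 ± 34.5 against 2795 ± 269 CPM (adjusted p = 1.98e-08 and 0.00566).

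The other genes with the highest changes among those separating all libraries were Arhgap36 (7.14), Hapln1 (6.61), Shisa3 (6.38), the secreted Wnt inhibitor Sfrp1 (6.37) and Upk1b, which had 2 counts in all DPP4+ libraries together (ratio 412, counting interval 114 to 3400). Those with the lowest were the mast cell protease genes Tpsb2 (-8.83), Cma1 (-7.53) and Cpa3 (-7.21), the serotonin receptor gene Htr1f (-7.42) and Cfd, which encodes adipsin (-7.03, adjusted p = 0.0008). Cfd was at 100.2 ± 91.1 CPM in the inguinal progenitors, and its call was lost with limma-voom library weights (-5.10, adjusted p = 0.133). The mast cell genes were highest in inguinal progenitor library 2, where Tpsb2 was at 93.2 CPM against 20.7 and 18.99 in the others. Among the fixed genes, Prdm16 (1.54), Ebf2 (1.19), Cebpa (3.11), Adipoq (2.22) and Acta2 (1.63) were also higher in perivascular progenitors. Pdgfra (0.26, adjusted p = 0.536), Fabp4 (0.24, adjusted p = 0.699), Myh11 (-0.31, adjusted p = 0.694) and Tagln (-0.12, adjusted p = 0.927) did not pass. Myh11 was at 78.8 CPM in inguinal progenitor library 2 against 25.4 and 22.7 in the others. Without the 3 libraries that stood apart (that one and the perivascular libraries 1 of both stages) Myh11 turned to 0.87 (adjusted p = 0.0133) and Pdgfra was called (0.56, adjusted p = 0.0268). Dpp4 was at 1507 ± 72.6 CPM in the inguinal cells sorted for it and at 89.3 ± 7.55 in perivascular progenitors, which is no finding because the sort used it. Icam1 did not pass (0.64, adjusted p = 0.0505) but was called with the replicate block (0.67, adjusted p = 0.0448) and without inguinal progenitor library 2 (0.78, adjusted p = 0.0481), perivascular preadipocyte library 1 (0.61, adjusted p = 0.0174) or 3 (0.61, adjusted p = 0.044). It was also called with library totals as the scale (1.06, adjusted p = 0.00307), the stricter filter (adjusted p = 0.0471), DESeq2 (0.0479), limma-voom weights (0.00371), the 2 groups alone (0.0469) and without the 3 libraries (0.00203).

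Of 20 progenitor marker genes, 19 were lower in perivascular progenitors (20 adjusted over the list alone). Their median was -2.46 (adjusted p = 1.03e-38, and 0.00753 with an estimated correlation). The list holds Dpp4, which the inguinal sort used. Akr1c18 (-6.89), Wnt2 (-4.23) and Dact2 (-3.94) were examples. All 28 tested cell cycle genes were higher on both adjustments (median 2.39, adjusted p = 1.94e-42, and 0.00753 with an estimated correlation). Ccnb1 was at 96.0 ± 3.70 against 10.7 ± 1.05 CPM, Bub1b at 3.09 and Aurkb at 2.97. Of 11 genes of Hox paralogue groups 1 to 5, 10 were higher (11 adjusted over the list alone; median 2.11, adjusted p = 2.65e-08), among them Hoxa2 (5.80), Hoxb5 (4.54) and Hoxa5 (4.50). Of 6 genes of groups 9 to 13, 4 were lower on both adjustments (median -3.30, adjusted p = 1.20e-12), with Hoxa10 at -6.43 and Hoxc9 at -4.68. In groups 6 to 8, 4 of 7 were higher and 1 lower on both adjustments (median 1.25, adjusted p = 0.0918), and the list was called without perivascular progenitor library 3 (adjusted p = 0.0312). Of 20 limb and body wall transcription factors, 13 were lower and 3 higher on both adjustments (median -2.72, adjusted p = 2.76e-11). Irx3 had no count in perivascular progenitors and was at least 50-fold lower, Irx5 at least 29.9-fold lower, and the list's median was unchanged with such genes at their bound. Mesothelial markers moved with these lists: 11 of 14 were higher, and 1 lower when adjusted over the list alone (median 3.66, adjusted p = 1.21e-11), with the mesothelin gene Msln at 57.2 ± 16.4 against 0.951 CPM.

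Preadipocyte markers had 12 of 20 members higher and 1 lower (14 and 1 adjusted over the list alone; median 1.20, adjusted p = 0.000211, and adjusted p = 0.0797 with an estimated correlation), with Col15a1 at 3.93 and Sparcl1 at 2.44. Thermogenic genes had 9 of 20 higher and 1 lower (11 and 1 adjusted over the list alone; median 1.37, adjusted p = 0.000295, and adjusted p = 0.306 with an estimated correlation), with the deiodinase gene Dio2 at 3.56 and Esrrg at 2.67. Retinoid genes had 8 of 18 higher and 1 lower on both adjustments (median 0.84, adjusted p = 0.00214, and 0.114 with an estimated correlation). The retinaldehyde dehydrogenase genes Aldh1a2 (4.13) and Aldh1a3 (-3.66) went opposite ways. Early-response genes, which tissue digestion can induce, had 13 of 22 lower and 1 higher on both adjustments (median -0.79, adjusted p = 1.36e-10, and 0.0877 with an estimated correlation), with Hspa1a at 20.6 ± 2.01 against 274 ± 28.2 CPM. The list passed with that correlation plus the replicate block. Haematopoietic markers had 11 of 18 lower (13 adjusted over the list alone; median -1.89, adjusted p = 0.00022, and adjusted p = 0.568 with an estimated correlation), with C1qb at -2.48. That list's call was lost without 3 libraries that stood apart (adjusted p = 0.102), an alternative chosen after seeing the data. Matrix genes had 9 of 28 lower and 4 higher (12 and 4 adjusted over the list alone; median -0.60, adjusted p = 0.0256, and adjusted p = 0.766 with an estimated correlation), with Fn1 at -2.86 and Mfap4 at 2.28. That call was lost without perivascular progenitor library 1 (adjusted p = 0.109). Mitochondrially encoded genes had 5 of 13 higher (7 adjusted over the list alone; median 0.76, adjusted p = 0.0434, and adjusted p = 0.758 with an estimated correlation), a call lost with the replicate block (adjusted p = 0.053), with library totals as the scale (0.0561) and without inguinal progenitor library 2 (0.0673) or perivascular progenitor library 1 (0.106). Thymus genes had 2 of 6 lower, Krtdap (-5.05) and Cd3e (-2.09), and the list fell by its test (adjusted p = 0.0105, and adjusted p = 0.0797 with an estimated correlation) with a mean of -1.04 but a median of 0.19.

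The remaining lists did not pass between the progenitors. Adipocyte and lipid genes had 6 higher and 2 lower of 22 on both adjustments, with a median of -0.14, a mean of 0.21 and a median of 0.29 with library totals as the scale (adjusted p = 0.374), and Car3 at 5.28 and Gpd1 at 3.51. Of 36 nuclear oxidative phosphorylation genes edgeR called 0, with 3 at an unadjusted p under 0.05, while DESeq2 called 0 and limma-voom 5. Transcription factors of the cardiac outflow tract and neural crest had 6 of 16 higher and 1 lower (8 and 2 adjusted over the list alone; adjusted p = 0.0605), with Foxc1 at 4.87 and Foxc2 at 4.76. That list was called without DPP4+ library 1 (adjusted p = 0.0477) or 3 (0.0308), ICAM1+ library 1 (0.0445), 2 (0.041) or 3 (0.0453), or perivascular progenitor library 2 (0.0116) or 3 (0.00805). Chemokine and complement genes had 10 of 23 higher and 7 lower on both adjustments, with Il33 at 4.86 and Cxcl2 at -4.18. Growth factor genes of the IGF list had 6 of 20 higher and 7 lower on both adjustments, with Igfbp7 at 4.37 and Igfbp6 at -2.91. Signalling lists were divided as well: 8 higher and 8 lower of 25 BMP genes, 5 and 5 of 20 TGF-beta genes, and 6 and 4 of 29 Wnt genes (9 and 9, 8 and 5, and 6 and 5 adjusted over the list alone).

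The test called 4687 genes between the progenitors (24.9% of those tested), 2459 higher and 2228 lower in perivascular cells, of which 3157 changed at least 2-fold. With library totals as the scale the median log2 fold change of all genes was 0.48 instead of 0.05, and 7546 genes were called, 83.7% of them higher instead of 52.5%. Changes above are relative to the TMM scale.

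**Figure D2:**
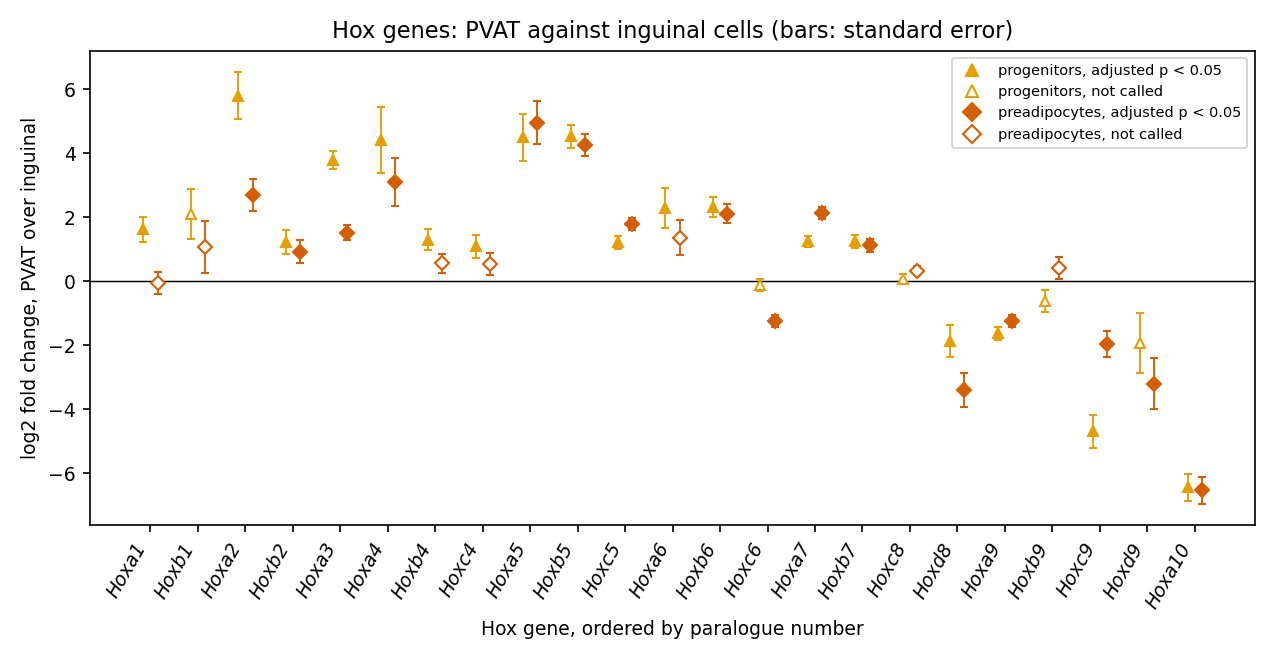
Log2 fold change of perivascular over inguinal cells (vertical, bars are standard errors) for 23 Hox genes (horizontal, in order of paralogue group), for progenitors and for preadipocytes. Filled points had an adjusted p under 0.05, as Hoxa5 did at 4.50 and 4.96 and Hoxa10 at -6.43 and -6.53.

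Perivascular preadipocytes were set against ICAM1+ inguinal preadipocytes. Ucp1 was at 161 ± 85.1 CPM in perivascular and 0.625 ± 0.0646 in inguinal preadipocytes (log2 7.99, adjusted p = 1.14e-06). Cidea, a lipid droplet protein gene of brown fat (chromosome 18, 67343604 to 67367785), was at 46.6 ± 23.4 against 0.25 ± 0.189 CPM (log2 7.54, adjusted p = 3.92e-06). Adipoq, the adiponectin gene (chromosome 16, 23146536 to 23158028), was at 762 ± 397 against 27.7 ± 5.91 CPM (log2 4.78, adjusted p = 0.000129). Cebpa, a transcription factor of adipogenesis (chromosome 7, 35119293 to 35121928), was at 31.5 ± 17.3 against 3.08 ± 0.347 CPM (adjusted p = 0.000254). The Ly6 gene Ly6a, which encodes SCA1 (chromosome 15, 74994877 to 74998031), was lower at 4.17 ± 0.888 against 841 ± 47.5 CPM (log2 -7.65, adjusted p = 2.14e-08).

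The insulin receptor substrate gene Irs4 (9.05), Thrsp (6.99), the lipid droplet gene Plin5 (6.86) and Myl7 (6.81) were also among the highest. Npy2r (-7.62), Ly6c1 (-6.90) and Ifi205 (-6.84) were among the lowest, and Hoxc10 had 1 count in all perivascular preadipocyte libraries (ratio 1220.0, counting interval 219 to 48300.0). Prdm16 (2.39), Ebf2 (1.01), Pparg (1.11) and Fabp4 (1.79) were higher, and Cd55 (-3.48) and Pdgfra (-1.84) lower. Pi16 (1.04, adjusted p = 0.0563), Myh11 (-0.77, adjusted p = 0.208), Acta2 (0.46, adjusted p = 0.263) and Tagln (0.16, adjusted p = 0.836) did not pass. Pi16 was called without perivascular preadipocyte library 2 (1.27, adjusted p = 0.045) or 3 (1.37, 0.00615). Library 1 of that group carried most of the difference. It held 103.5 CPM, against 36.75 and 21.52 in libraries 2 and 3 and 22.4 to 29.5 in ICAM1+ libraries. Pi16 was also called with library totals as the scale (1.24, adjusted p = 0.0235), DESeq2 (1.02, 0.0384) and limma-voom weights (0.48, 0.0261). Myh11 was called without the 3 libraries that stood apart (-0.82, adjusted p = 0.00474) and with the 2 groups alone (-0.85, adjusted p = 0.0165). Acta2 was called with limma-voom weights (0.57, adjusted p = 0.0228). Icam1 was at 496 ± 11.1 CPM in the inguinal cells sorted for it and 39.4 ± 11.9 in the perivascular cells. Dpp4 was lower in perivascular preadipocytes (-2.65).

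**Figure D3:**
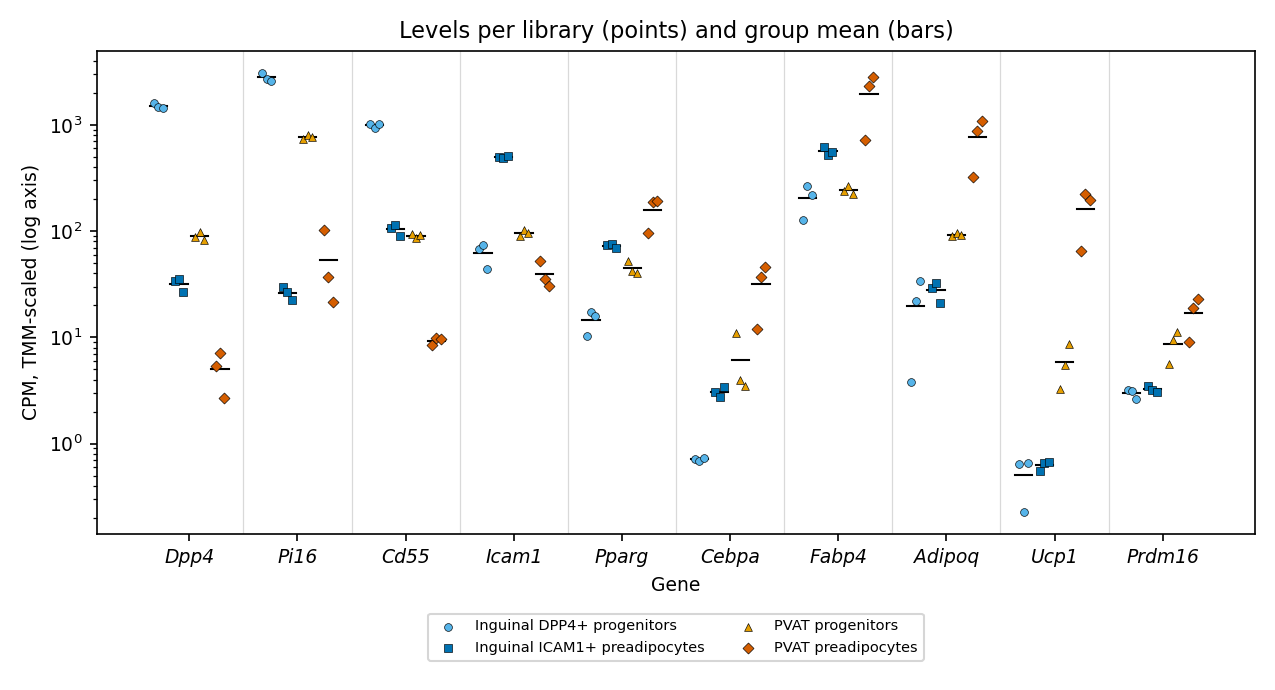
TMM-scaled CPM (vertical, log axis) of 10 fixed genes (horizontal) in each library, with the sorted populations side by side for each gene. Points are libraries and bars are group means, and Ucp1 was between 64.7 and 225 CPM in the 3 perivascular preadipocyte libraries.

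Of 20 thermogenic genes, 17 were higher and 1 lower in perivascular preadipocytes on both adjustments (median 3.63, adjusted p = 3.36e-11, and 0.0626 with an estimated correlation). The list passed with that correlation plus the replicate block. Cox7a1 (5.23) and the mitochondrial coactivator gene Ppargc1a (5.02) were examples. Of 36 nuclear oxidative phosphorylation genes, 35 were higher (36 adjusted over the list alone; median 1.70, adjusted p = 4.83e-17, and adjusted p = 0.206 with an estimated correlation), among them Uqcrfs1 (3.15), Cox5a (3.10) and Cycs (2.84). Mitochondrially encoded genes had 12 of 13 higher (13 adjusted over the list alone; median 1.24, adjusted p = 0.000142, and adjusted p = 0.349 with an estimated correlation), and adipocyte and lipid genes 16 of 22 (19, with 2 lower, adjusted over the list alone; median 2.24, adjusted p = 3.12e-09, and adjusted p = 0.155 with an estimated correlation). In the latter list Car3 was at 5.62, Gpd1 at 5.58 and the leptin gene Lep at 4.83. These 4 lists were lower in perivascular preadipocyte library 1 than the mean of the other 2 of its group, with medians of -1.29, -1.23, -1.14 and -1.13. Ucp1 was at 64.7 CPM in that library against 225 and 195. All 28 cell cycle genes were higher on both adjustments (median 1.75, adjusted p = 2.40e-22, and 0.0371 with an estimated correlation). Ccna2 was at 2.87 and Birc5 at 2.72.

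Chemokine and complement genes had 17 of 23 lower and 3 higher on both adjustments (median -1.91, adjusted p = 5.28e-15), with Ccl19 at -5.19, Ccl2 at -4.12 and Il6 at 4.50 ± 0.469 against 96.8 ± 11.6 CPM. Interferon response genes had 16 of 22 lower on both adjustments (median -1.14, adjusted p = 1.20e-06), with the antiviral genes Oas1a at -3.23 and Mx2 at -2.12. IGF and growth factor genes had 14 of 20 lower and 1 higher (14 and 2 adjusted over the list alone; median -0.86, adjusted p = 5.13e-06), with Igfbp6 at -3.11 and the imprinted H19 at -2.48. Progenitor markers had 15 of 20 lower (15, with 1 higher, adjusted over the list alone; median -1.497, adjusted p = 5.28e-15), with Akr1c18 at -4.20. Early-response genes had 18 of 22 lower and 1 higher on both adjustments (median -1.39, adjusted p = 4.83e-17), with Hspa1a at -3.63 and Egr3 at -3.51. Matrix genes had 17 of 28 lower and 2 higher (18 and 4 adjusted over the list alone; median -1.21, adjusted p = 4.78e-06, and adjusted p = 0.349 with an estimated correlation) and basement membrane genes 12 of 20 lower on both adjustments (median -1.43, adjusted p = 9.56e-06, and adjusted p = 0.206 with an estimated correlation). Fn1 (-2.84), Col6a3 (-2.40) and Col18a1 (-3.12) were examples. The matrix genes were higher in perivascular preadipocyte library 1 than the mean of the other 2 of its group (median 1.10).

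Of the positional lists, Hox groups 1 to 5 had 7 of 11 genes higher on both adjustments (median 1.52, adjusted p = 0.000219, and adjusted p = 0.0494 with an estimated correlation), a call lost with an estimated correlation and the replicate block together (adjusted p = 0.0792), with Hoxa5 (chromosome 6, 52201754 to 52204587) at 41.9 ± 11.5 against 1.33 CPM. Hox groups 9 to 13 had 5 of 6 lower on both adjustments (median -2.58, adjusted p = 2.16e-08), with Hoxa10 at -6.53 and Hoxd9 at -3.20, and groups 6 to 8 had 3 of 7 higher and 2 lower (5 and 2 adjusted over the list alone; adjusted p = 0.181). Limb and body wall factors had 11 of 20 lower and 2 higher on both adjustments (median -2.31, also with genes at their bound, adjusted p = 1.46e-08), with Tbx15 at 1.06 against 78.7 ± 3.71 CPM and En1, without a count in perivascular preadipocytes, at least 83.6-fold lower. Outflow tract and neural crest factors had 10 of 16 higher and 3 lower on both adjustments (median 1.64, adjusted p = 0.0418, and adjusted p = 0.359 with an estimated correlation), with Foxc2 at 5.12 and Tbx1 at 4.41. That call was lost without perivascular preadipocyte library 1 (adjusted p = 0.15) and with library totals as the scale (0.0676).

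Markers of other cell types moved too. Epithelial markers had 11 of 14 lower on both adjustments (median -2.91, also with genes at their bound, adjusted p = 1.03e-05, and 0.0733 with an estimated correlation), with the keratin gene Krt5 at least 46.3-fold lower. The list passed with that correlation plus the replicate block. Schwann and neural markers had 9 of 15 lower and 3 higher (10 and 3 adjusted over the list alone; median -1.27, also with genes at their bound, adjusted p = 0.00139, and adjusted p = 0.206 with an estimated correlation), with Mbp at -4.14 and Th at least 43.5-fold higher. Mesothelial markers had 9 of 14 higher and 4 lower on both adjustments (median 3.35, adjusted p = 0.00139, and 0.206 with an estimated correlation). Wt1 was at 6.01 and Upk1b at 5.75. Haematopoietic markers had 8 of 18 lower (9 adjusted over the list alone; median -1.32, adjusted p = 0.012, and adjusted p = 0.529 with an estimated correlation), a call lost without perivascular preadipocyte library 1 (adjusted p = 0.0525). Erythroid genes had 4 of 5 lower on both adjustments (median -1.98, adjusted p = 0.0243, and 0.349 with an estimated correlation). Hbb-bt was at -2.59. Pericyte markers had 3 of 10 lower on both adjustments (median -0.65, adjusted p = 0.0169, and 0.206 with an estimated correlation). Vtn was at -3.14. Thymus genes had 3 of 6 lower on both adjustments (median -1.58, adjusted p = 0.00511, and 0.0524 with an estimated correlation). Cartilage and tendon genes had 7 of 14 higher and 1 lower on both adjustments (median 1.81, adjusted p = 0.0328, and adjusted p = 0.106 with an estimated correlation), with the tendon factor gene Scx at 4.02. That call was lost without perivascular preadipocyte library 1 (adjusted p = 0.0604) and with library totals as the scale (0.0676).

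The test called 8467 genes between the preadipocytes (44.9%), 4423 higher and 4044 lower in perivascular cells, of which 5506 changed at least 2-fold. With library totals as the scale the median of all genes was 0.27 instead of 0.04, and 66.5% of the called genes were higher instead of 52.2%. In both depot comparisons, which share pools but no library, 1207 genes were higher in perivascular cells and 1422 lower (independent lists: 577 and 478). In opposite directions 314 were called (independent lists: 1050.0). With library totals as the scale 4064 were called in both in the same direction.

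Within perivascular fat, preadipocytes were set against progenitors. Perivascular preadipocytes held more Ucp1, at 161 ± 85.1 against 5.80 ± 2.71 CPM (log2 4.798, adjusted p = 5.60e-05), and more Cidea, at 46.6 ± 23.4 against 1.93 ± 0.926 CPM (log2 4.59, adjusted p = 0.000124). Fabp4, a fatty acid carrier gene, was at 1959 ± 1103 against 242 ± 21.2 CPM (log2 3.02, adjusted p = 0.000462). Cfd (chromosome 10, 79890853 to 79892655) had the largest increase of the genes that met the rule for naming, to 75.5 ± 28.2 from 0.755 ± 0.383 CPM (log2 6.63, adjusted p = 0.00154). Ly6a had the largest decrease of these, to 4.17 ± 0.888 from 437 ± 105 CPM (log2 -6.71, adjusted p = 5.66e-08), and Pi16 fell to 53.9 ± 43.6 from 773 ± 34.5 CPM (log2 -3.84).

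Cox8b (5.24), the mitochondrial gene Chchd10 (4.43) and the potassium channel gene Kcnk3 (4.34) also rose. Ly6c1 (-5.59), the renin gene Ren1 (-4.52), Krtdap (-4.45), Akr1c18 (-4.37) and Cadm3 (-4.16) fell. Of the fixed genes, Pparg (1.82), Cebpa (2.35) and Adipoq (3.05) rose, and Dpp4 (-4.13), Cd55 (-3.28), Pdgfra (-1.76) and Icam1 (-1.28) fell. Ebf2 (-0.14, adjusted p = 0.584), Myh11 (0.12, adjusted p = 0.876) and Acta2 (0.83, adjusted p = 0.0653) did not pass, though Acta2 was called without inguinal progenitor library 2 (0.83, adjusted p = 0.00861) or 3 (0.83, adjusted p = 0.0452). Acta2 was also called with library totals as the scale (0.999, adjusted p = 0.038), DESeq2 (adjusted p = 0.0464), limma-voom weights (0.00645), the 2 groups alone (0.0485) and without the 3 libraries that stood apart (0.54, adjusted p = 0.0145). Prdm16, a regulator of brown fat identity (chromosome 4, 154316125 to 154636873), was called at 0.96 (adjusted p = 0.0367). That call was lost without perivascular preadipocyte library 2 (0.86, adjusted p = 0.116) or 3 (0.64, adjusted p = 0.199), perivascular progenitor library 1 (0.66, adjusted p = 0.105) or 2 (0.97, adjusted p = 0.0846), or ICAM1+ library 1 (adjusted p = 0.0512), 2 (0.0521) or 3 (0.0513), and with the 2 groups alone (0.119). Tagln (1.82, adjusted p = 0.0446) shares 67.9% of its exon length with another gene and is uncertain, and its call was lost with the replicate block (1.90, adjusted p = 0.0635), no filter (adjusted p = 0.0598), the 2 groups alone (0.0776) and without the 3 libraries that stood apart (0.95, adjusted p = 0.279). It was also lost without inguinal progenitor library 2 (adjusted p = 0.0563), ICAM1+ library 1 (0.0634), 2 (0.06) or 3 (0.0601), perivascular preadipocyte library 1 (0.135) or 2 (0.105), and perivascular progenitor library 1 (0.121) or 3 (0.118).

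All 20 progenitor markers fell on both adjustments (median -2.57, adjusted p = 5.19e-43, and 0.0064 with an estimated correlation). IGF and growth factor genes had 12 of 20 fall and 1 rise on both adjustments (median -0.94, adjusted p = 1.04e-06), with Igfbp5 at -3.55. The other called lists did not hold with an estimated correlation. All 36 nuclear oxidative phosphorylation genes rose on both adjustments (median 1.63, adjusted p = 7.54e-25, and 0.23 with an estimated correlation). Cox5a was at 3.09 and Uqcrfs1 at 2.91. Adipocyte and lipid genes had 18 of 22 rise (18, with 1 fall, adjusted over the list alone; median 2.34, adjusted p = 3.13e-11, and adjusted p = 0.185 with an estimated correlation), with Cidec at 3.76, Retn at 3.54 and Plin1 at 3.53. Thermogenic genes had 14 of 20 rise and 1 fall (15 and 1 adjusted over the list alone; median 1.75, adjusted p = 2.21e-09, and adjusted p = 0.146 with an estimated correlation). Mitochondrially encoded genes had 10 of 13 rise (12 adjusted over the list alone; median 1.11, adjusted p = 0.000376, and adjusted p = 0.412 with an estimated correlation). All 28 cell cycle genes rose on both adjustments (median 1.03, adjusted p = 4.22e-16, and 0.136 with an estimated correlation), with Ccna2 at 1.99. In perivascular preadipocyte library 1 the oxidative phosphorylation list was lower than the mean of the other 2 libraries (median -1.23), and the progenitor list higher (median 0.57).

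Matrix genes had 18 of 28 fall (20 adjusted over the list alone; median -1.08, adjusted p = 3.82e-11, and adjusted p = 0.286 with an estimated correlation) and basement membrane genes 9 of 20 on both adjustments (median -0.66, adjusted p = 0.000624, and adjusted p = 0.41 with an estimated correlation), with Fn1 at -2.29, Fbln2 at -1.93 and Nid1 at -1.58. Chemokine and complement genes had 15 of 23 fall and 2 rise on both adjustments (median -1.05, adjusted p = 1.86e-06, and adjusted p = 0.0939 with an estimated correlation), with C4b at -2.22 and Il33 at -1.88. Interferon response genes had 10 of 22 fall and 2 rise on both adjustments (median -0.91, adjusted p = 0.000581, and adjusted p = 0.0939 with an estimated correlation). TGF-beta genes had 9 of 20 fall on both adjustments (median -0.53, adjusted p = 0.00522, and 0.412 with an estimated correlation). Tgfbi was at -1.55. BMP genes had 10 of 25 fall and 1 rise (11 and 1 adjusted over the list alone; median -0.57, adjusted p = 0.0113, and adjusted p = 0.41 with an estimated correlation), with Bmp7 at -3.88 and the BMP antagonist gene Grem1 at -2.82. Wnt genes had 7 of 29 fall and 3 rise on both adjustments (median -0.39, adjusted p = 0.0212, and adjusted p = 0.41 with an estimated correlation), with Wnt2 at -3.40, Wnt10b at -3.23 and Sfrp5 at 3.50. The BMP and Wnt calls were lost without perivascular progenitor library 1 (adjusted p = 0.287 and 0.473). Retinoid genes had 6 of 18 fall and 2 rise (8 and 3 adjusted over the list alone; median -0.48, adjusted p = 0.0153, and adjusted p = 0.277 with an estimated correlation), with Aldh1a3 at -2.99 and Rxrg at 2.90. Mesothelial markers had 7 of 14 fall and 1 rise on both adjustments (median -1.35, adjusted p = 0.00293, and 0.288 with an estimated correlation). Msln was at -2.51. Thymus genes had 1 of 6 fall on both adjustments, Krtdap (median -0.55, adjusted p = 0.0153, and 0.137 with an estimated correlation). The retinoid and thymus calls were lost without perivascular preadipocyte library 1 (adjusted p = 0.0834 and 0.0637).

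Preadipocyte markers had 7 of 20 rise and 4 fall (9 and 4 adjusted over the list alone; adjusted p = 0.183), with Cd36 at 2.60. The 3 Hox lists did not pass, with 1 of 11 lower in groups 1 to 5 (0 adjusted over the list alone) and, on both adjustments, 2 of 7 higher in groups 6 to 8 and 2 of 6 higher in groups 9 to 13 (Hoxc9 at 3.00 and Hoxa9 at 0.85). Limb and body wall factors had 2 of 20 higher and 4 lower on both adjustments, with a median of -0.14, a mean of 0.09, a median of -0.10 with genes at their bound and a median of 0.02 with library totals as the scale. Early-response genes had 6 of 22 lower (4 adjusted over the list alone; adjusted p = 0.127), and the list was called without perivascular preadipocyte library 1 (adjusted p = 0.0134). Of 18 haematopoietic markers edgeR called 0, with 1 at an unadjusted p under 0.05 and 1 each by DESeq2 and limma-voom.

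The test called 6198 genes between the stages in perivascular fat (32.9%), 3168 higher and 3030 lower in preadipocytes, of which 3414 changed at least 2-fold. The count was 4028 without perivascular preadipocyte library 2, 3964 without library 3 and 3915 without perivascular progenitor library 3. It was 2825 in a fit of the 2 perivascular groups alone, 10913 with limma-voom weights and 9894 without the 3 libraries that stood apart. With library totals as the scale the median of all genes was 0.12 instead of -0.05, and 66.3% of the called genes were higher instead of 51.1%.

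**Figure D4:**
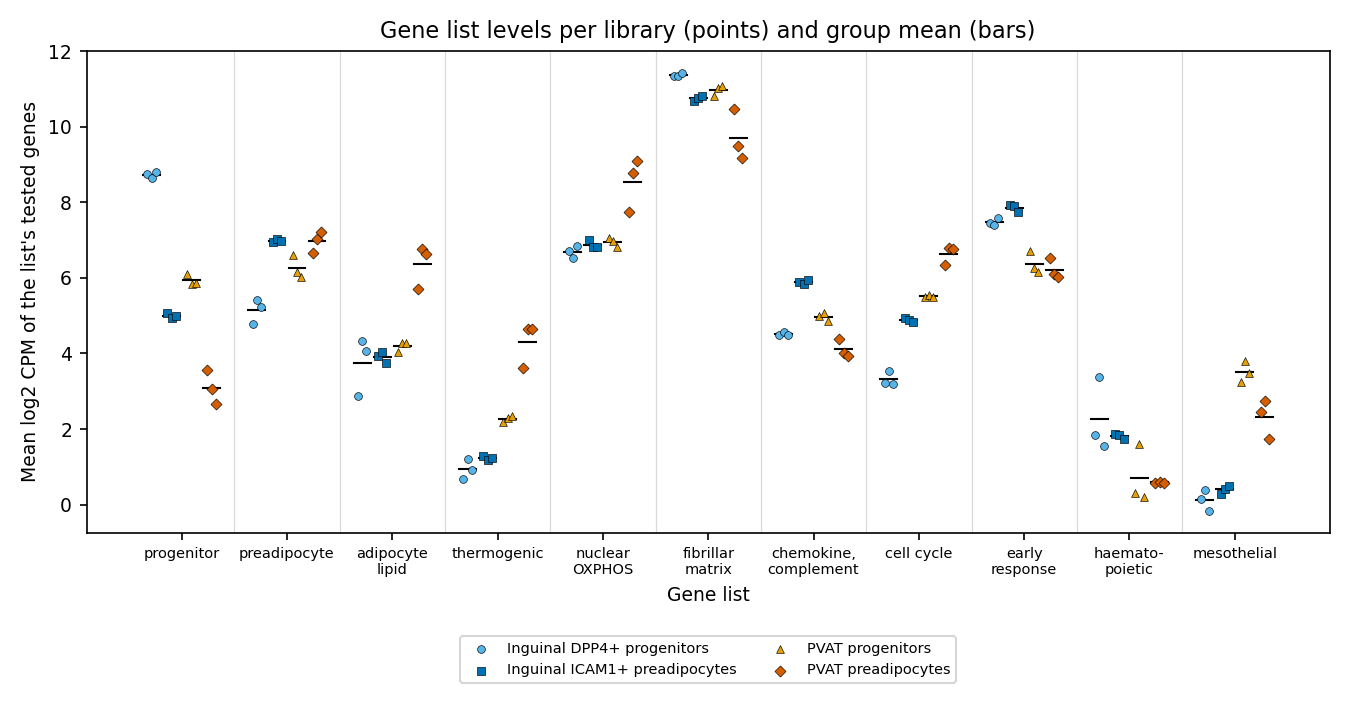
Mean log2 CPM (vertical) of the tested genes of 11 lists (horizontal) in each library, with the groups side by side for each list. Points are libraries and bars are group means, and all 36 oxidative phosphorylation genes rose from perivascular progenitors to preadipocytes.

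Within inguinal fat, ICAM1+ preadipocytes were set against DPP4+ progenitors. ICAM1+ preadipocytes held more of the basement membrane collagen gene Col15a1 (chromosome 4, 47208161 to 47313167), at 196 ± 21.1 against 5.64 ± 2.62 CPM (log2 5.12, adjusted p = 3.47e-06), and more of the prolactin receptor gene Prlr, at 141 ± 9.71 against 4.90 ± 2.27 CPM (log2 4.85, adjusted p = 2.40e-07). Pparg rose to 73.0 ± 3.19 from 14.4 ± 3.64 CPM (log2 2.34, adjusted p = 5.31e-05). Pi16 fell to 26.2 ± 3.56 from 2795 ± 269 CPM (log2 -6.74, adjusted p = 2.45e-06), and Bmp7 to 0.688 from 98.8 ± 22.1 CPM (log2 -7.18, adjusted p = 1.02e-05). Ucp1 was at 0.625 ± 0.0646 and 0.508 ± 0.243 CPM (log2 0.31, adjusted p = 0.833), and Adipoq did not pass (0.49, adjusted p = 0.634) but was called with limma-voom weights (1.40, adjusted p = 0.0361).

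Gdpd2 (4.597), Cited1 (4.32), the hedgehog inhibitor gene Hhip (4.20) and Npy2r (4.20) also rose. The GABA receptor gene Gabra2 (chromosome 5, 70957597 to 71095849; -7.38), Dync1i1 (-7.29), Akr1c18 (-7.06) and Wnt10b (-6.98) fell. Of the fixed genes, Acta2 rose to 234 ± 28.8 from 58.1 ± 35.2 CPM (2.01, adjusted p = 0.001) and Cd55 fell (-3.26). Prdm16 (0.11, adjusted p = 0.876), Ebf2 (0.04, adjusted p = 0.904), Pdgfra (0.34, adjusted p = 0.46), Myh11 (0.58, adjusted p = 0.473) and Tagln (1.53, adjusted p = 0.144) did not pass. Myh11 was called without inguinal progenitor library 2 (1.40, adjusted p = 0.0483) and without the 3 libraries that stood apart (1.38, adjusted p = 0.000301). Tagln was called with library totals as the scale (1.90, adjusted p = 0.0477) and limma-voom weights (2.01, adjusted p = 0.0238). Cebpa was called at 2.10 (adjusted p = 0.0264), a call lost without DPP4+ library 1 (adjusted p = 0.0824), 2 (0.0807) or 3 (0.074) and without ICAM1+ library 1 (0.0567), 2 (0.0505) or 3 (0.0686). Fabp4 was called at 1.47 (adjusted p = 0.021), a call lost without DPP4+ library 1 (adjusted p = 0.0895) or 3 (0.0559) and without ICAM1+ library 1 (0.0633) or 3 (0.0525). Dpp4 (-5.56) and Icam1 (3.01) were used in these sorts and are no finding.

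All 20 progenitor markers fell on both adjustments (median -3.24, adjusted p = 8.04e-69). Preadipocyte markers had 14 of 20 rise and 1 fall (15 and 1 adjusted over the list alone; median 1.99, adjusted p = 1.81e-15), with the angiotensinogen gene Agt at 3.98 and Aoc3 at 3.15. These lists hold Dpp4 and Icam1, and how far the sorts set both results was not tested. All 28 cell cycle genes rose on both adjustments (median 1.58, adjusted p = 5.13e-29), with Cenpf and Top2a at 2.01. Chemokine and complement genes had 16 of 23 rise (18, with 1 fall, adjusted over the list alone; median 1.17, adjusted p = 3.21e-13), with Cxcl13 at 6.21 and Il33 at 2.16. Ccl19 had 1 count in all DPP4+ libraries (ratio 173, counting interval 30.8 to 6860.0). Matrix genes had 8 of 28 fall and 2 rise on both adjustments (median -0.47, adjusted p = 0.00167, and 0.765 with an estimated correlation). Mfap5 and Fn1 were at -2.30. Basement membrane genes had 6 of 20 rise and 2 fall (7 and 5 adjusted over the list alone; adjusted p = 0.146), with Col4a1 at 2.77 and Col4a2 at 2.62. Wnt genes had 7 of 29 rise and 7 fall (7 and 10 adjusted over the list alone) with a median of -0.30 that was 0.08 with library totals as the scale (adjusted p = 0.0251, and adjusted p = 0.612 with an estimated correlation), and Wnt2 was at -4.03 and Wnt6 at 3.12. BMP genes had 4 of 25 rise and 8 fall on both adjustments (adjusted p = 0.38), with Bmp6 at -5.83 and Bmp4 at -4.20.

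Smooth muscle genes had 6 of 18 rise and 1 fall (7 and 1 adjusted over the list alone; median 0.92, adjusted p = 0.000847, and adjusted p = 0.521 with an estimated correlation), with Actg2 at 1.94. Pericyte markers had 5 of 10 rise and 2 fall (6 and 2 adjusted over the list alone; median 1.19, adjusted p = 0.00176, and adjusted p = 0.154 with an estimated correlation), with Steap4 at 4.14 and Notch3 at 2.68. Epithelial markers had 3 of 14 rise (7 adjusted over the list alone; median 1.10, also with genes at their bound, adjusted p = 0.00501, and adjusted p = 0.408 with an estimated correlation), with Krt14 at 3.72. Endothelial markers had 1 of 16 fall on both adjustments, Tek at -3.14 (median -0.59, adjusted p = 0.0258, and adjusted p = 0.765 with an estimated correlation). That call was lost without inguinal progenitor library 2 (adjusted p = 0.205) or ICAM1+ library 1 (0.0526), and all 16 endothelial genes were higher in inguinal progenitor library 2 than the mean of the other 2 of its group (median 0.90). Schwann and neural markers had 4 of 15 rise (5 adjusted over the list alone; median 0.51, adjusted p = 0.0505), and the list was called with the replicate block (adjusted p = 0.011). It was also called without inguinal progenitor library 2 (adjusted p = 0.000934), ICAM1+ library 2 (0.0408) or 3 (0.0339), perivascular preadipocyte library 2 (0.0239), or perivascular progenitor library 1 (0.0348), 2 (0.0344) or 3 (0.0496). Adipocyte and lipid genes had 3 of 22 rise and 3 fall (3 and 5 adjusted over the list alone), with a median of 0.07 and a mean of -0.10 (adjusted p = 0.987). Thermogenic genes had 2 of 20 rise and 1 fall on both adjustments (adjusted p = 0.401), with Cox8b at 3.97 and Lhx8 at 3.55. Of 36 nuclear oxidative phosphorylation genes edgeR called 0, with 0 at an unadjusted p under 0.05, while DESeq2 called 0 and limma-voom 4. Retinoid genes had 6 of 18 rise and 1 fall (7 and 3 adjusted over the list alone; adjusted p = 0.674), with Aldh1a2 at 2.69 and Aldh1a3 at -5.52.

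The test called 3384 genes between the inguinal stages (17.9%), 1761 higher and 1623 lower in preadipocytes, of which 2401 changed at least 2-fold. With library totals as the scale the median of all genes was 0.40 instead of 0.02, and 5281 genes were called, 82.7% of them higher instead of 52.0%. The count was 5757 in a fit of the 2 inguinal groups alone and 6052 with limma-voom weights. In both stage comparisons, which share pools but no library, 465 genes rose and 776 fell (independent lists: 296 and 261). In opposite directions 307 were called (independent lists: 556). The genes called the same way in both were 2816 with limma-voom weights and 2213 without the 3 libraries that stood apart.

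The interaction asked whether the change from progenitor to preadipocyte differed between the depots, with positive values for a higher change in perivascular fat. Ucp1 changed more in perivascular fat (difference 4.49, adjusted p = 0.00696), as did Cidea (5.40), the leptin gene Lep (5.29) and Cox7a1 (4.55). Cxcl13 (-6.82, adjusted p = 1.58e-05), Vit (-6.35), Col15a1 (-5.67) and Ly6a (-5.46) had the lowest differences of the named genes, and Vit was at 4.26 ± 1.45 CPM in perivascular preadipocytes and 33.5 ± 5.52 in perivascular progenitors. Cfd (9.10, adjusted p = 0.00176), Gabra2 (6.80), Cidec (6.76) and Ccdc68 (5.95) had the highest. Pi16 fell in both depots, by less in perivascular fat (difference 2.89, adjusted p = 0.00666).

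Pdgfra (-2.10) differed as well. Icam1 (-4.29) and Dpp4 (1.43, adjusted p = 0.0207) go with the inguinal sorts and are no finding, and the call of Dpp4 was lost without ICAM1+ library 3 (1.31, adjusted p = 0.0632), perivascular preadipocyte library 2 (1.09, adjusted p = 0.0647) or perivascular progenitor library 3 (1.36, adjusted p = 0.0534). Adipoq was called at 2.56 (adjusted p = 0.0498) but not with the replicate block (2.06, adjusted p = 0.11), with library totals as the scale (2.34, adjusted p = 0.0639) or with the stricter filter (2.48, adjusted p = 0.0543). Its call was also lost without DPP4+ library 2 (adjusted p = 0.0897) or 3 (0.143), ICAM1+ library 1 (0.0934), 2 (0.0889) or 3 (0.121), perivascular preadipocyte library 2 (0.107) or 3 (0.104), and perivascular progenitor library 2 (0.0879) or 3 (0.0969). Prdm16 (0.85, adjusted p = 0.239), Ebf2 (-0.18, adjusted p = 0.653), Pparg (-0.52, adjusted p = 0.334), Cebpa (0.25, adjusted p = 0.859), Fabp4 (1.55, adjusted p = 0.0774), Cd55 (-0.02, adjusted p = 0.951), Myh11 (-0.46, adjusted p = 0.673), Acta2 (-1.18, adjusted p = 0.1) and Tagln (0.29, adjusted p = 0.863) did not pass. Acta2 was called without inguinal progenitor library 2 (-1.80, adjusted p = 0.00304), and Prdm16 (1.12, adjusted p = 0.0484) and Fabp4 (1.91, adjusted p = 0.00119) without perivascular preadipocyte library 1. Without the 3 libraries that stood apart Cebpa (1.34, adjusted p = 0.0153), Fabp4 (1.64, adjusted p = 0.000231), Prdm16 (0.84, adjusted p = 0.0413), Myh11 (-1.69, adjusted p = 0.000799) and Acta2 (-2.06, adjusted p = 9.36e-06) were called. Fabp4 was also called with DESeq2 (adjusted p = 0.032). With limma-voom weights Fabp4 (0.0016), Prdm16 (0.0473) and Acta2 (0.00621) were called.

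Chemokine and complement genes had 19 of 23 with a lower change in perivascular fat (20 adjusted over the list alone; median -2.28, and -2.13 without genes at the count floor, adjusted p = 6.13e-24), with Ccl19 at -6.48, Il33 at -4.05 and C4b at -3.44. Preadipocyte markers had 9 of 20 lower (9, with 1 higher, adjusted over the list alone; median -1.04, adjusted p = 5.47e-08), with Aoc3 at -3.30. That list holds Icam1. IGF and growth factor genes had 7 of 20 lower (8 adjusted over the list alone; median -0.89, adjusted p = 1.78e-05), with Igf1 at -2.89 and Fgf7 at -2.30. Interferon response genes had 10 of 22 lower (11 adjusted over the list alone; median -1.06, adjusted p = 7.61e-06), with Isg15 at -2.67. Nuclear oxidative phosphorylation genes had 31 of 36 with a higher change in perivascular fat (35 adjusted over the list alone; median 1.45, adjusted p = 1.36e-16, and adjusted p = 0.344 with an estimated correlation), with Cox5a at 2.79 and Uqcrfs1 at 2.75. Adipocyte and lipid genes had 13 of 22 higher (14 adjusted over the list alone; median 2.16, adjusted p = 6.77e-09, and adjusted p = 0.341 with an estimated correlation), with Pnpla2 at 3.43. Thermogenic genes had 8 of 20 higher and 1 lower (9 and 1 adjusted over the list alone; median 1.69, adjusted p = 3.67e-05, and adjusted p = 0.344 with an estimated correlation). Basement membrane genes had 7 of 20 lower (9 adjusted over the list alone; median -0.88, adjusted p = 7.61e-06, and adjusted p = 0.344 with an estimated correlation), with Col4a1 at -3.01 and Nid2 at -2.60.

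The test called 2834 genes for the interaction (15.0%), 1201 with a higher and 1633 with a lower change in perivascular fat. The count was 1844 without DPP4+ library 3, 1666 without ICAM1+ library 2, 1706 without ICAM1+ library 3, 1714 without perivascular preadipocyte library 2 and 1812 without perivascular progenitor library 3. It rose to 5234 without perivascular preadipocyte library 1 and 4847 without perivascular progenitor library 1. It was 7784 without the 3 libraries that stood apart and 8384 with limma-voom weights. With library totals as the scale the median of all genes was -0.21 instead of -0.0032, and 23.3% of the called genes were then higher instead of 42.4%.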

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

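All tests of the libraries that stood apart, and for the early-response genes the tests of scaling, of haematopoietic cells over all progenitor libraries and of those in the ICAM1+ sort, were chosen only after the result was seen, while the splits of the libraries and the other tests of the early-response genes were planned.

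The interaction of depot and stage called 2834 genes. The gene lists were tested apart from that count, against all other genes on the same difference, which called 18 of 33 lists, and 4 of these also with an estimated correlation. The lists that differed, as the median log2 change in perivascular less inguinal fat, include preadipocyte (-1.04), IGF and growth (-0.89), chemokine and complement (-2.28) and interferon response (-1.06), which were also called with an estimated correlation. Adipocyte and lipid (2.16), thermogenic (1.69), nuclear oxidative phosphorylation (1.45) and basement membrane genes (-0.88) were called too, but with adjusted p = 0.341, 0.344, 0.344 and 0.344 with an estimated correlation. Progenitor markers differed by 0.79 (7 of 20 higher and 1 lower, 10 and 1 adjusted over the list alone), with adjusted p = 0.454 with an estimated correlation and 0.188 without perivascular preadipocyte library 1. Mitochondrially encoded genes differed by 0.64 with edgeR calling 0 of 13, 2 at an unadjusted p under 0.05, DESeq2 1 and limma-voom 9, and with adjusted p = 0.692 with an estimated correlation. The list's adjusted p was 0.0615 with the replicate block, 0.0592 and 0.0525 without DPP4+ libraries 1 and 3, 0.0885 without ICAM1+ library 2, 0.0847 and 0.242 without perivascular preadipocyte libraries 2 and 3, and 0.106 and 0.0723 without perivascular progenitor libraries 1 and 3, and 0.0503 with library totals as the scale. Matrix genes differed by -0.60 (4 of 28 lower, 5 adjusted over the list alone), with adjusted p = 0.692 with an estimated correlation and 0.0828 without perivascular preadipocyte library 3. Cell cycle genes differed by -0.40 (7 of 28 lower, 10 adjusted over the list alone), with adjusted p = 0.661 with an estimated correlation and 0.183 without perivascular preadipocyte library 1. Early-response genes differed by -0.60 (8 of 22 lower, 9 adjusted over the list alone), with adjusted p = 0.444 with an estimated correlation and 0.0778 without perivascular progenitor library 1.

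Retinoid genes differed by -0.57 (1 of 18 higher and 7 lower, 3 and 8 adjusted over the list alone), with adjusted p = 0.344 with an estimated correlation, 0.134 and 0.0515 without DPP4+ libraries 1 and 2 and 0.0666 without perivascular preadipocyte library 1. Pericyte markers differed by -0.65 (1 of 10 higher and 2 lower on both adjustments), with adjusted p = 0.296 with an estimated correlation. Schwann and neural markers differed by -0.60 (-0.61 without genes at the count floor; 2 of 15 lower on both adjustments), with adjusted p = 0.444 with an estimated correlation, 0.0543 without DPP4+ library 1 and 0.0755 without perivascular preadipocyte library 3. Mesothelial markers differed by -1.63 (-1.27 without genes at the floor; 5 of 14 lower on both adjustments), with adjusted p = 0.344 with an estimated correlation. Epithelial markers differed by -1.40 (-1.26 without genes at the floor; 2 of 14 lower, 3 adjusted over the list alone), with adjusted p = 0.444 with an estimated correlation, 0.117 and 0.0759 without perivascular preadipocyte libraries 1 and 3 and 0.0962 with library totals as the scale.

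Of the named genes, the change in perivascular fat was higher for Adipoq (2.56), Akr1c18 (2.70), Bmp7 (3.30), Ccdc68 (5.95), Cfd (9.10), Chchd10 (5.70), Cidea (5.40), Cidec (6.76), Cma1 (4.88), Cpa3 (3.95), Dpp4 (1.43), Dync1i1 (4.64), Gabra2 (6.80), Kcnk3 (4.69), Pi16 (2.89), Plin5 (5.40), Thrsp (3.32), Tpsb2 (5.17), Ucp1 (4.49) and Wnt10b (3.75). It was lower for Cited1 (-2.33), Col15a1 (-5.67), Cxcl13 (-6.82), Gdpd2 (-5.30), Hapln1 (-3.15), Hhip (-4.75), Icam1 (-4.29), Ifi205 (-2.70), Ly6a (-5.46), Ly6c1 (-4.01), Npy2r (-4.93), Pdgfra (-2.10), Prlr (-4.95), Ren1 (-4.71), Sfrp1 (-2.77), Shisa3 (-4.40) and Vit (-6.35). Dpp4 and Icam1, members of lists above, go with the inguinal sorts and are no finding. Besides Adipoq and Dpp4, described above, calls were lost for Kcnk3 without DPP4+ library 2 (adjusted p = 0.0537) and for Bmp7 without DPP4+ library 3 (0.0588), ICAM1+ library 2 (0.0728) or 3 (0.0641), or perivascular preadipocyte library 1 (0.0757) or 2 (0.0506). For Sfrp1 the call was lost without DPP4+ library 1 (adjusted p = 0.0562), 2 (0.0536) or 3 (0.077), ICAM1+ library 1 (0.0518), 2 (0.0689) or 3 (0.0551), or perivascular preadipocyte library 2 (0.064) or 3 (0.059).

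Of 100 drawn splits of the libraries, 1 gave as many called genes for the interaction, the real one. The other splits mixed progenitors with preadipocytes within a depot, which widens the spread within groups where the stages differ. They therefore cannot decide whether chance gave the interaction count. The highest other split called 1387. The numbers pair the libraries by pool, and the 16 drawn splits that part all pools as the real one does are too few for a share under 0.05. Among these the highest other was also 1387, against 1215 among the rest. For the other 4 comparisons the 10 possible splits are too few for a share under 0.05. The real split was the 1 with as many called genes in each: 4687, 8467, 6198 and 3384 genes against a highest other of 0, 0, 125 and 0, both over all splits and over the 4 that part all pools.

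Perivascular preadipocyte library 1 lay toward the progenitors, with adipocyte, lipid and thermogenic genes at a median ratio of 0.428 (95% interval over genes 0.368 to 0.469, 38 genes) to the mean of the other 2 libraries. Ly6a, Ly6c1 and Pi16 implied progenitor RNA shares of 0.0502%, -0.409% and 9.99%, less than the ratio of 0.4279 would need. The sort markers are not given and may include these genes, so progenitors mixed in stay open. Matrix genes setting the scale are excluded, since the ratio was 0.4282 with these genes taken out. A less adipogenic pool of mice stays open: in its progenitor library the genes of these lists with at least 5 CPM there had a median log2 ratio of -0.3627 (interval -0.667 to -0.0486, 27 genes, not the same set). Against it, nuclear oxidative phosphorylation genes had a median log2 ratio of 0.1261 there (interval 0.1 to 0.201, 36 genes), while they were lower in the preadipocyte library, and Cebpa and Pparg were higher there too.

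Haematopoietic genes were higher in inguinal progenitor library 2 than the mean of the other 2 DPP4+ libraries, by a median log2 ratio of 1.687 (interval 1.32 to 1.89, 17 genes), and mast cell genes by 1.74 (interval 0.833 to 2.24, 10 genes). Erythroid genes rose by only 0.5462 (range 0.252 to 0.641, 4 genes), which cannot exclude blood left in the tissue if red cells were removed. Haematopoietic cells in the sort, mast cells among them, may be the source, with Tpsb2 at 93.2 CPM, Lyz2 at 83.4 CPM and Cma1 at 73.7 CPM in that library, and a sort that excludes such cells would remove them. Whether the sort did so is not known here. The perivascular progenitor library of the same pool was also higher for the haematopoietic list (mean log2 CPM 1.59 against 0.30 and 0.21), so a source shared by pool 2 stays open and was not tested.

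Early-response genes were lower in both perivascular populations, with adjusted p = 0.0877 among the progenitors and 0.0302 among the preadipocytes with an estimated correlation. Both passed with that correlation plus the replicate block. The planned bound for scaling, a median under -0.5 under all 3 scalings, was missed with library totals among the progenitors (-0.3575), so a measure that no scaling factor moves was used instead: the list's median less that of all genes was -0.8482 (interval -1.22 to -0.469, 22 genes) where it was nearest 0, which argues against scaling as the whole cause. Among the progenitors the median was -0.8531 without inguinal progenitor library 2, though the other DPP4+ libraries hold haematopoietic RNA too, and the depot difference in the list's mean log2 CPM over all 6 libraries was -1.248 with the haematopoietic list as a term (-1.313 to -1.172 on leaving out 1 library) and -1.113 without it, which argues against such cells as the whole cause there. Those in the ICAM1+ sort stay open for the preadipocytes, because the haematopoietic list varied by only 0.1286 (log2) among the ICAM1+ libraries. The mean log2 CPM of the list in perivascular less inguinal libraries was -1.382, but dissociation and depot coincide and cannot be told apart, and a biological difference between the depots stays open.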

How the results depend on the processing

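The fit without 3 libraries that stood apart and the list tests with the replicate block and an estimated correlation were chosen after seeing the data, and all other alternatives were planned. Leaving out 1 library at a time gave 3605 to 5762 called genes between the progenitors, 6614 to 9574 between the preadipocytes, 3915 to 8001 between the perivascular stages, 2276 to 4292 between the inguinal stages and 1666 to 5234 for the interaction. It gave 2012 to 3245 genes called in both depot comparisons in the same direction, 846 to 1847 in both stage comparisons and 80 to 87 called lists. Median-of-ratios size factors, no filter, the stricter filter and DESeq2 left the gene counts within 1.5 times the reported ones.

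Library totals as the scale gave 7546 genes between the progenitors, 5281 between the inguinal stages and 4064 in both depot comparisons. An adjusted p under 0.01, which is stricter by construction, gave 2822, 5508, 3170, 1956 and 1059 genes in the 5 comparisons, 1454 in both depot and 609 in both stage comparisons. At least a 2-fold change left 5506 genes between the preadipocytes and 3414 between the perivascular stages. Fits of only the 2 groups compared gave 2825 genes between the perivascular and 5757 between the inguinal stages, with the spread taken from 6 libraries instead of 12 and the filter leaving 17453 and 16639 genes instead of 18855. The limma-voom weights gave 10913 genes between the perivascular and 6052 between the inguinal stages, 8384 for the interaction and 2816 in both stage comparisons, with the lowest weights of 0.197 and 0.248 on the perivascular libraries of pool 1. Without the 3 libraries the counts were 9894 between the perivascular stages, 7784 for the interaction and 2213 in both stage comparisons, and Myh11 reversed between the progenitors to 0.87 (adjusted p = 0.0133). With an estimated correlation 25 lists were called, and 27 with the replicate block added, which ended 1 of the 25 (Hox groups 1 to 5 between the preadipocytes, adjusted p = 0.0792). Newly called were thermogenic and epithelial genes there and early-response genes between the progenitors. Apart from the stricter threshold, the cause was not tested.

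With the replicate block the counts were 4195, 7885, 5486, 2988 and 2158. The block ended 22 named-gene calls and made 1, and ended 2 list calls and made 1. Among named-gene results, library totals ended 21 calls and made 4, DESeq2 ended 2 and made 4, and leaving out 1 library ended 9 to 50 and made 0 to 4. Of the 165 list tests, fry ended 7 calls and made 16, and no filter made 15. The stricter filter left 20 of these tests without enough genes, made 1 call and ended 10. It ended those of haematopoietic (adjusted p = 0.1), mitochondrially encoded (0.1) and matrix genes (0.0685) between the progenitors, and of haematopoietic (0.296), outflow tract (0.0992) and pericyte genes (0.0557) between the preadipocytes. It also ended those of BMP genes between the perivascular stages (0.0918), endothelial genes between the inguinal stages (0.0584), and mitochondrially encoded (0.108) and retinoid genes (0.0752) for the interaction. In simulated data with the depth of these libraries and the same spread in all groups, 1.49% to 32.8% of 2-fold changes were recovered. Recovery in the real data may differ, and a missing call is not read as the absence of such a change. How far depth sets this limit was not tested.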

Other observations

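All values here were read after the comparisons were made, and no test was added for them. Markers of other cell types not described above stayed mostly below a call. Smooth muscle genes had 6 of 18 higher and 2 lower in perivascular than inguinal progenitors on both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.23), with the integrin gene Itga8 at 4.16 and Mustn1 at -2.97. That list was called without inguinal progenitor library 2 (adjusted p = 0.0127). Skeletal myogenic genes had 2 of 7 higher between the progenitors on both adjustments, with a median of -0.41, a mean of 0.26 and a median of 0.03 with library totals as the scale (adjusted p = 0.77). Between the preadipocytes 2 of 7 were higher on both adjustments (median 0.57, adjusted p = 0.255), with the cardiac actin gene Actc1 at 5.71. Cartilage and tendon genes had 5 of 14 higher and 1 lower between the progenitors on both adjustments (median 0.94, adjusted p = 0.116), with Fmod at 3.26 and Col2a1 at -3.66. Endothelial markers had 1 of 16 higher and 4 lower between the progenitors on both adjustments (median -0.24, and 0.18 with library totals as the scale, adjusted p = 0.144), with Vwf at 1.53 and Tek at -2.58. That list was called without DPP4+ library 1 (adjusted p = 0.00973) or perivascular progenitor library 3 (0.0463). Erythroid genes had 3 of 5 lower between the progenitors on both adjustments (median -1.501, adjusted p = 0.169).

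In inguinal progenitor library 2, all 22 adipocyte and lipid genes were also higher than the mean of the other 2 DPP4+ libraries (median log2 ratio 0.72), as were most Schwann and neural markers (1.21) and smooth muscle genes (0.81). The adipocyte and lipid list's mean log2 CPM was 2.86, 4.32 and 4.07 in DPP4+ libraries 1, 2 and 3. In perivascular progenitor library 1, outflow tract factors (0.72) and Wnt genes (0.74) were higher and basement membrane genes (-0.82) lower, by these medians, than the mean of the other 2 libraries of its group.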
